A study of Mus musculus with 47 samples.

How the data were processed

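The deposited table holds estimated counts per gene for 47 libraries, made by the authors with Salmon 1.9.0 against mouse GRCm38 after trimming with Trim Galore 0.6.4, per the submitters' processing notes. The values in the table are whole numbers, so they were used as counts without further rounding. Libraries were assigned to 6 groups from the labels, and 0 columns were left unmapped. The labels call the untreated AMLN group NASH vehicle, and the design notes state that 1 of 8 chow samples was left out by the submitters at quality control. Male C57BL/6 mice were used, and RNA came from liver biopsies of 15 to 20 mg.

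The table holds 19168 genes, each with a total of at least 5 counts in at least 5 libraries. Of these, 19153 identifiers matched GENCODE M21, 18772 of them with the same version, and 15 did not match. Coordinates are GRCm38, counted from 1. Of the gene symbols, 32 occur more than once, and those genes were kept apart by their identifiers. The lowest chi-square per degree of freedom between any 2 libraries of a group was 13.17, so no library is a technical repeat of another by that measure. Library totals ranged from 4910000 to 24300000 counts.

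Genes were tested with edgeR 4.0.16 (quasi-likelihood F test) in R 4.3.3 with limma 3.58.1. All 47 libraries were fitted together with 1 mean per group, TMM factors and the filterByExpr filter, which kept 14153 genes. The common dispersion was 0.0559, a biological coefficient of variation of 0.236, with 41 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes, and log2 CPM for components and scores used a prior count of 2. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

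The comparisons are AMLN vehicle with chow, each treated group with AMLN vehicle, each NN1177 dose with semaglutide, the high with the low dose, and the high dose and semaglutide with chow. They were fixed with their alternatives before the data were examined, as were 45 gene lists (1099 entries written from general knowledge of liver biology) and 23 panel genes. Lists with at least 3 tested members were tested, which left 44. The list test is camera with a preset correlation of 0.01, and its p-values were adjusted over the 44 lists within a comparison. Camera with the correlation estimated per list and fry were the alternatives. List counts adjusted over the list alone use Benjamini-Hochberg over the members only.

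Genes were named by a rule: the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 5 CPM, up to 4 called members of each list by adjusted p, and the 23 panel genes. The text takes some of these, at most 30 per comparison from the highest, lowest and panel genes, and gives a few further levels of the same genes in other groups.

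The alternatives for every comparison were DESeq2 size factors, no filter beyond a total above 0, a mean of at least 1 CPM, the DESeq2 1.42.0 Wald test, limma-voom with library quality weights, the 2 groups alone, number range as a covariate, and each library left out in turn. Scaling by library totals only, leaving out the 2 libraries with under 8000000 counts, leaving out number range D (6 libraries), range A or range B, and keeping only the libraries in number series were chosen after the data had been seen. Number ranges come from gaps between the numbers in the sample titles, and no label says that they are batches. The labels carry no replicate numbers that link groups, so no pairing was planned. The title numbers step through the groups in series, and a fit with the series as a block was also added after the data had been seen. Replicate numbers in the text are the order of libraries within a group.

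The tests were run on simulated data with known changes between the high-dose and AMLN vehicle libraries. EdgeR recovered 64.2% of 67 genes changed 1.5-fold, 94.0% of 67 changed 2-fold and 100% of 66 changed 4-fold, with 4 false calls among 13906 genes run. DESeq2 recovered 71.6%, 95.5% and 100% with 14 false calls, and limma-voom 65.7%, 92.5% and 98.5% with 6. A list made to change was found by camera at adjusted p = 3.5e-47 with the preset and adjusted p = 1.25e-18 with an estimated correlation, with 0 false calls by camera among the 43 lists run. The simulated genes varied independently of one another, whereas the estimated correlation among ribosomal protein genes in the real data was 0.78 between the diets. This run therefore could not show false list calls that come from correlation within a list.

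Comparisons that share a control were set against 20 simulations in which the drug groups had the AMLN vehicle means, and against 20 random halvings of the AMLN vehicle libraries, with separate libraries for each comparison. Each comparison was also repeated on 24 random regroupings of its own libraries. Raw reads were not processed, as only the count table was available. Genes with near-identical copies (Mup, Cyp2c, Cyp3a, Serpina1) were examined as sums over the family too, since Salmon divides shared reads between copies. The receptor list could not be tested because too few of its members passed the filter.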

Results

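RNA was sequenced from liver biopsies of male C57BL/6 mice in 6 groups, giving 47 libraries. Mice on chow received vehicle (n = 7; the submitters' design notes state that 1 further sample was excluded at quality control). Mice on the AMLN diet, a fat-, fructose- and cholesterol-rich diet used to induce steatohepatitis, received vehicle, NN1177 at a low, a medium or a high dose, or semaglutide (n = 8 in each group). The series title describes NN1177 as a long-acting agonist of the GLP-1 and glucagon receptors, and semaglutide is a GLP-1 receptor agonist. The labels give no doses in units, so the 2 compounds are not known to have been given at matched doses. The title names the GAN diet where the design notes name AMLN, which is the name used here.

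Total counts per library ranged from 4910000 to 24300000, with a median of 16000000. The lowest and highest totals by group were 6900000 and 22200000 on chow, 9640000 and 21200000 in AMLN vehicle, and 8100000 and 22500000 at the low dose. They were 4910000 and 23300000 at the medium dose, 9550000 and 24300000 at the high dose, and 10900000 and 20800000 on semaglutide. Of 19168 genes in the table, 14153 had enough counts to be tested. Levels are given as CPM (counts scaled by library size), mean ± SD over the libraries of a group, and changes as log2 fold change ± standard error with edgeR's adjusted p. The p-values measure the spread between samples, since the labels do not say whether each library came from a separate animal. Coordinates are on GRCm38.

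The first principal component (30.5% of the variance) ran from AMLN vehicle (-40.6 ± 10.6) to chow (70.5 ± 9.9), and the second (13.4%) set the high dose apart (48 ± 5.8 against -14.3 ± 6.3 in AMLN vehicle). On the first component, the medium dose (3.3 ± 23.2), the high dose (13.9 ± 16.3) and semaglutide (-9.9 ± 27.1) lay between AMLN vehicle and chow. The glucagon receptor gene Gcgr was expressed in every group, at 165 ± 16.2 CPM on chow and 121 ± 10.9 CPM in AMLN vehicle (log2 -0.45 ± 0.09, adjusted p = 2.37e-05, turning to 0.06 and adjusted p = 0.351 with library totals). The GLP-1 receptor gene Glp1r reached no more than 8 counts in any library and was not tested, and the GIP receptor gene Gipr was not in the table. The sample titles are numbers that fall into 4 ranges (A to D, of 20, 12, 9 and 6 libraries), and 1728 genes (12.2%) differed between the ranges given the group. Range A holds 2 chow, 2 AMLN vehicle and 4 libraries of each treated group, and range B holds 1, 3 and 2 of them, so values within A and within B are given beside the pooled ones. Direction was compared between each of these ranges and genes called without its libraries, a check added after the data had been seen. The shares over all tested genes, called or not, are given in parentheses, and were 59.2% and 45.5% for the low dose, where edgeR called 0 genes without either range.

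**Figure D1:**
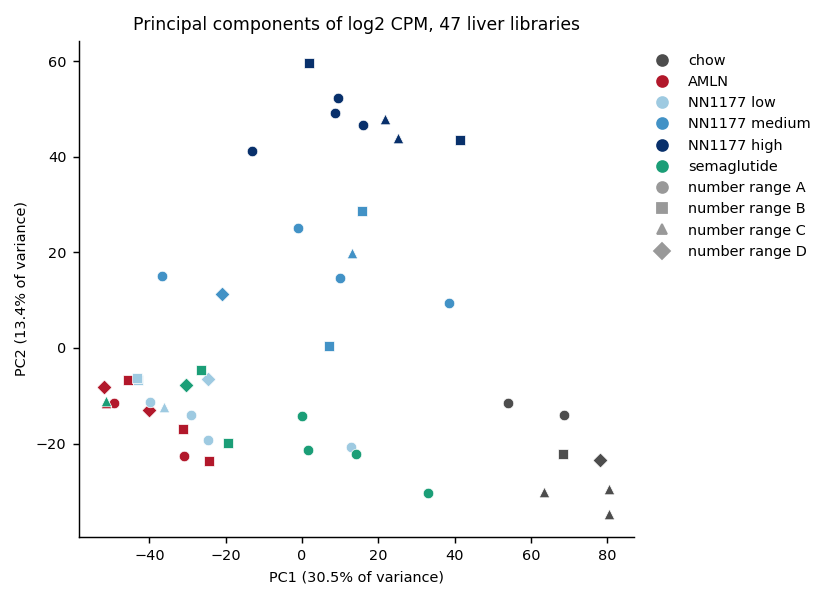
First against second principal component of log2 CPM, with 1 point per library, coloured by group and shaped by the range of the sample number. The chow libraries average 70.5 on the first component and AMLN vehicle averages -40.6, and the high-dose libraries average 48 on the second.

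The comparison of AMLN vehicle with chow asks what the diet did to the liver without drug. Collagen transcripts rose: Col1a1 (chromosome 11, 94936224 to 94953042) rose 21-fold from 9.8 ± 6.48 to 204 ± 54.2 CPM (log2 4.40 ± 0.40, adjusted p = 3.99e-12) and Col3a1 (chromosome 1, 45311538 to 45349706) rose 16-fold from 19.1 ± 8.33 to 304 ± 59.3 CPM (n = 7 and 8). Cidea (chromosome 18, 67343604 to 67367785), which encodes a protein that enlarges lipid droplets, rose from 0.161 ± 0.229 to 34.8 ± 8.95 CPM (log2 7.82 ± 0.66, adjusted p = 6.69e-13). Gpnmb (chromosome 6, 49036546 to 49070929) and Mmp12, both expressed by activated macrophages, rose by log2 6.17 ± 0.53 and 6.00 ± 0.51. Gnmt (chromosome 17, 46725664 to 46729168), which encodes the glycine methyltransferase, fell from 2540 ± 397 to 490 ± 87.8 CPM, and Cps1 (chromosome 1, 67123026 to 67231259), which encodes the entry enzyme of the urea cycle, fell from 4190 ± 796 to 1380 ± 294 CPM.

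Among the gene lists fixed in advance, 45 of 48 extracellular matrix genes rose and 2 fell on the AMLN diet (45 and 2 adjusted over the list alone; camera adjusted p = 8.38e-28), with Loxl2, a collagen cross-linking enzyme, up by log2 2.81 ± 0.26 and Timp1, a metalloproteinase inhibitor, by 4.75 ± 0.49. The smooth muscle actin gene Acta2 was at 5.31 ± 0.858 against 4.52 ± 4.39 CPM (adjusted p = 0.501). Of 29 markers of recruited macrophages 25 rose and none fell (25 adjusted over the list alone; camera adjusted p = 2.06e-16), among them Trem2, a lipid receptor of macrophages, by log2 4.67 ± 0.45. Antigen presentation genes rose in 15 of 16 cases (15 adjusted over the list alone; camera adjusted p = 1.2e-11), with H2-Aa up 8.70-fold. Proliferation genes rose in 28 of 32 cases and 1 fell (28 and 1 adjusted over the list alone; camera adjusted p = 2.61e-14), with Mki67 (chromosome 7, 135689784 to 135716361) at 11.5 ± 3.78 against 1.14 ± 0.609 CPM. All 18 bile duct markers rose (18 adjusted over the list alone; camera adjusted p = 1.04e-06). With an estimated correlation these list calls were lost: adjusted p = 0.0746 for matrix, antigen presentation and proliferation, adjusted p = 0.106 for recruited macrophages and adjusted p = 0.311 for bile duct markers.

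Cholesterol synthesis genes fell in 24 of 25 cases (25 adjusted over the list alone; camera adjusted p = 7.45e-16, adjusted p = 0.0746 with an estimated correlation), including Hmgcr, the rate-limiting enzyme, from 198 ± 75.6 to 47 ± 11.4 CPM. Amino acid catabolism genes fell in 40 of 42 cases (40 down and 1 up adjusted over the list alone; camera adjusted p = 9.38e-16, adjusted p = 0.139 with an estimated correlation), with Agxt, a peroxisomal aminotransferase, down by log2 -2.27 ± 0.20. Hepatocyte markers fell in 25 of 27 cases (25 adjusted over the list alone; camera adjusted p = 7.86e-17, adjusted p = 0.0746 with an estimated correlation). Of 12 markers of resident Kupffer cells 3 rose and 5 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.32, adjusted p = 0.804 with an estimated correlation), and library totals turned the list's median from -0.31 to 0.22. The scavenger receptor genes Marco and Cd163 were among those that fell (log2 -5.61 ± 0.77 and -5.18 ± 0.81), and Clec4f was at 37.4 ± 21.3 against 47 ± 25.1 CPM (adjusted p = 0.545). Oxidative phosphorylation genes fell in 39 of 42 cases (39 adjusted over the list alone; camera adjusted p = 1.45e-08, adjusted p = 0.404 with an estimated correlation), a direction that turned to 6 higher and 2 lower with library totals in place of TMM factors.

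A total of 8110 genes differed between the diets, 3900 higher and 4210 lower on AMLN, of which 2367 and 567 by at least 2-fold. With library totals the split was 8612 higher and 711 lower, the median of all genes having moved from -0.06 to 0.45. Within range A 2799 genes and within range B 1591 genes were called, and 94.9% and 92.0% of the genes called without the range had the same direction within it (81.6% and 77.9% over all). The median log2 fold change within ranges A and B was 2.17 and 1.96 for matrix (pooled 2.52), -1.56 and -1.49 for cholesterol synthesis (pooled -1.35) and -0.96 and -0.58 for amino acid catabolism (pooled -0.95).

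NN1177 at the low dose against AMLN vehicle asks what the smallest dose did. The adipsin gene Cfd (chromosome 10, 79890853 to 79892655), usually expressed in adipocytes, was the 1 gene called: it fell from 12.9 ± 6.3 to 2.27 ± 1.36 CPM (log2 -2.48 ± 0.46, adjusted p = 0.0341, n = 8 and 8). The call was lost with the number range as a covariate (adjusted p = 0.114), and edgeR called 0 genes without replicate 3 or 8 of the low dose or replicate 5, 7 or 8 of AMLN vehicle. Col3a1 was at 203 ± 55.3 against 304 ± 59.3 CPM and Nnmt at 40.6 ± 11.6 against 38.3 ± 16.3 CPM, each with an adjusted p of 1. With no adjustment 556 genes (3.9%) had a p below 0.05, and DESeq2 called 1 gene, which was not Cfd, and limma-voom 2. Camera with its preset correlation called 23 of 44 lists, among them extracellular matrix (median log2 -0.29, 0 of 48 members called by edgeR and 0 adjusted over the list alone; adjusted p = 1.39e-11) and amino acid catabolism (median 0.20, 0 of 42 members and 2 higher adjusted over the list alone; adjusted p = 3.2e-13). Both lists had adjusted p = 0.433 with an estimated correlation, the lowest of any list, and no list passed with fry (lowest adjusted p = 0.486). The matrix median was -0.33 within range A and 0.08 within range B, and edgeR called 0 genes in either range.

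At the medium dose against AMLN vehicle, Gls2 (chromosome 10, 128194457 to 128210004), the liver glutaminase that releases ammonia, rose from 96.4 ± 25.3 to 485 ± 161 CPM (log2 2.33 ± 0.21, adjusted p = 3.16e-11, n = 8 and 8). Agxt (chromosome 1, 93135240 to 93145421) rose from 61.5 ± 10.1 to 300 ± 85.4 CPM. Col3a1 fell from 304 ± 59.3 to 58.3 ± 33.6 CPM (log2 -2.38 ± 0.31) and Cidea from 34.8 ± 8.95 to 8.36 ± 10.6 CPM. Rarres1 (chromosome 3, 67478972 to 67515523) fell by log2 -3.67 ± 0.23 and Cfd by -7.87 ± 0.75. Cyp2a4, a steroid hydroxylase with close copies in the genome, rose from 10.7 ± 8.72 to 186 ± 131 CPM.

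Of 42 amino acid catabolism genes 31 rose (31 up and 1 down adjusted over the list alone; camera adjusted p = 8.13e-21), with Gnmt up by log2 2.11 ± 0.21. Of 11 urea cycle genes 8 rose (10 up and 1 down adjusted over the list alone; camera adjusted p = 5.16e-10), with Cps1 up by 1.26 ± 0.18. Hepatocyte markers rose in 21 of 27 cases (21 adjusted over the list alone; camera adjusted p = 2.15e-14). Extracellular matrix genes fell in 38 of 48 (42 adjusted over the list alone; camera adjusted p = 7.25e-24). Interferon response genes fell in 24 of 33 cases (26 adjusted over the list alone; camera adjusted p = 1.59e-11), including Ifit3 by log2 -1.05 ± 0.18. These 5 lists had adjusted p = 0.129 with an estimated correlation. Proliferation genes fell in 25 of 32 cases and 1 rose (25 and 1 adjusted over the list alone; camera adjusted p = 3.73e-17, adjusted p = 0.066 with an estimated correlation), with Top2a, which untangles DNA in dividing cells, down by log2 -1.76 ± 0.26. Of 23 endothelial markers 12 fell (16 adjusted over the list alone; camera adjusted p = 2.55e-07, adjusted p = 0.241 with an estimated correlation), with Plvap, a marker of fenestrated vessels, at 31.1 ± 7.18 against 57.8 ± 7.95 CPM. Trem2 was at 8.97 ± 5.46 against 10.7 ± 3.59 CPM (adjusted p = 0.612).

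In all, 3760 genes differed at the medium dose, 1975 higher and 1785 lower, of which 173 and 428 by at least 2-fold. With library totals 700 were higher and 2908 lower, the median of all genes having moved to -0.17. Within ranges A and B, 312 and 669 genes were called, and 97.6% and 96.8% of the genes called without the range had the same direction within it (76.6% and 76.6% over all). Fewer were called then, 1830 without range A and 1682 without range B. The matrix median there was -0.85 and -1.28 (pooled -1.09) beside 0.66 and 0.74 for amino acid catabolism (pooled 0.66).

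At the high dose against AMLN vehicle, Gnmt rose 7.24-fold from 490 ± 87.8 to 3550 ± 646 CPM (log2 2.86 ± 0.21, adjusted p = 1.14e-14, n = 8 and 8), above the 2540 ± 397 CPM of chow livers. Gls2 rose from 96.4 ± 25.3 to 842 ± 107 CPM and Nnmt (chromosome 9, 48591877 to 48605153), which encodes nicotinamide N-methyltransferase, from 38.3 ± 16.3 to 372 ± 90.3 CPM (log2 3.28 ± 0.32, adjusted p = 3.08e-11). Cidea fell from 34.8 ± 8.95 to 0.206 ± 0.229 CPM (log2 -7.31 ± 0.58, adjusted p = 6.75e-14), close to its chow level of 0.161 ± 0.229 CPM. Col3a1 fell from 304 ± 59.3 to 29.7 ± 9.91 CPM (log2 -3.35 ± 0.32, adjusted p = 2.25e-11), against 19.1 ± 8.33 CPM on chow.

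**Figure D2:**
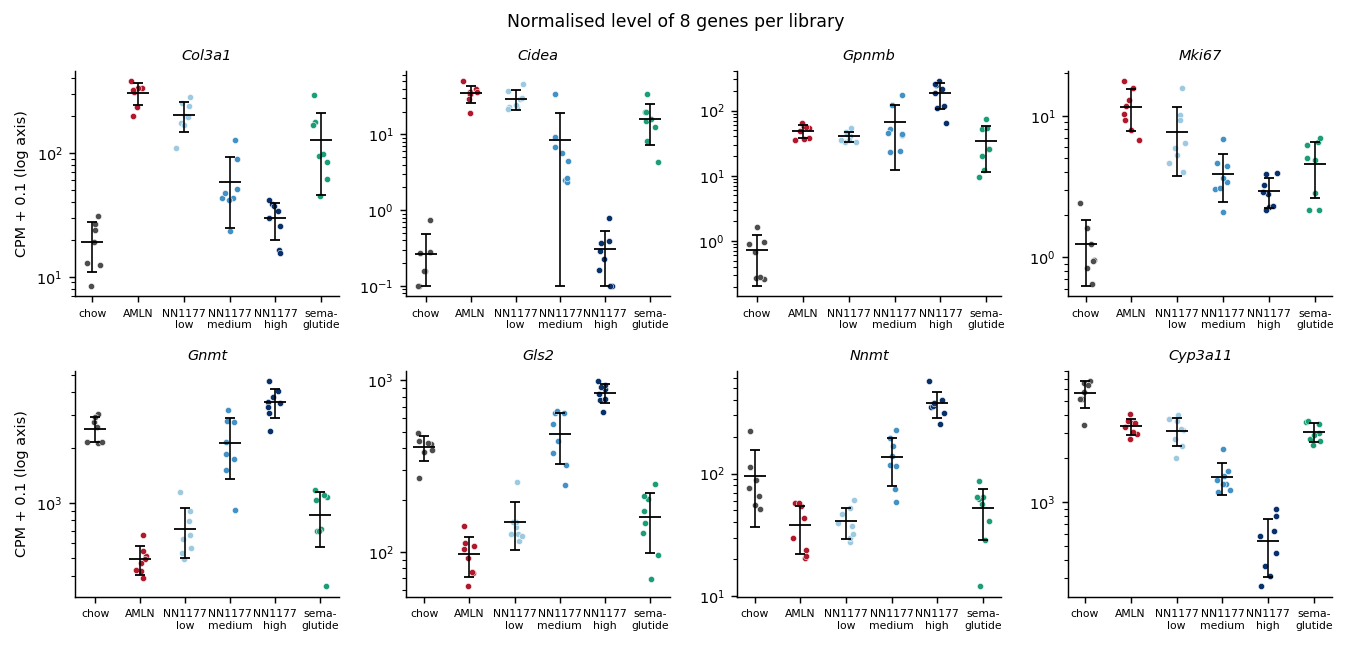
CPM plus 0.1 of 8 genes on log axes, with 1 point per library, the group mean as a line and ± 1 SD as bars drawn no lower than 0.1. Col3a1 averages 304 CPM in AMLN vehicle and 29.7 CPM at the high dose, while Gnmt averages 490 and 3550 CPM.

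Of 42 amino acid catabolism genes 32 rose and 3 fell at the high dose (33 and 3 adjusted over the list alone; camera adjusted p = 4.47e-19, adjusted p = 0.184 with an estimated correlation), with Agxt up by log2 2.76 ± 0.20. Of 11 urea cycle genes 9 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 4.85e-08, adjusted p = 0.184 with an estimated correlation), with Ass1, the argininosuccinate synthase, at 8080 ± 1420 against 1680 ± 359 CPM and Cps1 at 4150 ± 653 against 1380 ± 294 CPM. Amino acid transporters rose in 11 of 19 cases and 3 fell (11 and 3 adjusted over the list alone; camera adjusted p = 0.000919, adjusted p = 0.0927 with an estimated correlation). Oxidative phosphorylation genes rose in 37 of 42 cases (38 adjusted over the list alone; camera adjusted p = 5.12e-12, adjusted p = 0.435 with an estimated correlation), with Sdhd up 1.71-fold. Ribosomal protein genes rose in 30 of 34 (32 adjusted over the list alone; camera adjusted p = 3.41e-10, adjusted p = 0.498 with an estimated correlation). Oxidative phosphorylation had 24 higher and 4 lower with library totals, and ribosomal proteins 13 higher. Asns, which makes asparagine, and Atf5 rose by log2 2.83 ± 0.44 and 1.61 ± 0.17, within a list of 22 stress-response genes of which 5 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.317, adjusted p = 0.743 with an estimated correlation). That list's median turned from 0.05 to -0.24 with library totals. Pck1, a gluconeogenic enzyme, rose 2.66-fold, whereas the glucose-6-phosphatase gene G6pc was at 97.5 ± 58.6 against 171 ± 59.8 CPM (adjusted p = 0.143).

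Lipid droplet genes fell in 11 of 20 cases and 1 rose (15 and 3 adjusted over the list alone; camera adjusted p = 3.91e-08, adjusted p = 0.0662 with an estimated correlation), with Cidec down by log2 -4.77 ± 0.42 and Mogat1, which makes diacylglycerol, by -4.45 ± 0.33. Scd1, the stearoyl-CoA desaturase, fell from 30100 ± 8340 to 12600 ± 3530 CPM, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, from 121 ± 53.4 to 42.8 ± 29.9 CPM (log2 -1.51 ± 0.32, adjusted p = 0.000146). Hmgcr was at 36.2 ± 8.69 against 47 ± 11.4 CPM (adjusted p = 0.189) and Fgf21, a liver hormone, at 3.73 ± 1.86 against 2.58 ± 1.2 CPM (adjusted p = 0.252). Cyp3a11 (chromosome 5, 145854426 to 145879964), a major drug-metabolising P450 whose reads can be split with near-identical copies, fell from 3330 ± 424 to 534 ± 230 CPM.

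Of 48 extracellular matrix genes 42 fell at the high dose (42 down and 1 up adjusted over the list alone; camera adjusted p = 1.97e-19), and of 23 endothelial markers 22 fell (22 adjusted over the list alone; camera adjusted p = 5.41e-09). Cdh5, the vascular cadherin, was at 9.96 ± 1.62 against 24.6 ± 4.06 CPM. Stellate cell markers fell in 19 of 24 cases (20 adjusted over the list alone; camera adjusted p = 2.01e-08) and proliferation genes in 25 of 32, with 1 higher (25 and 1 adjusted over the list alone; camera adjusted p = 4.09e-10). These 4 lists had adjusted p = 0.184 with an estimated correlation. Interferon response genes fell in 28 of 33 cases (28 adjusted over the list alone; camera adjusted p = 5.1e-09, adjusted p = 0.207 with an estimated correlation). Hepatocyte markers rose in 22 of 27 cases and 1 fell (22 and 1 adjusted over the list alone; camera adjusted p = 1.55e-12, adjusted p = 0.184 with an estimated correlation). Gpnmb rose from 49.1 ± 11.3 to 184 ± 80.1 CPM (log2 1.91 ± 0.36), while the Kupffer marker Clec4f fell from 37.4 ± 21.3 to 13.4 ± 13 CPM (adjusted p = 0.00488). Trem2 was at 17.3 ± 7.28 against 10.7 ± 3.59 CPM (adjusted p = 0.0476), a call lost with DESeq2 size factors (adjusted p = 0.0558), the DESeq2 test (adjusted p = 0.0676) and library totals (adjusted p = 0.302). Of 29 recruited macrophage markers 6 rose and 3 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.922, adjusted p = 0.978 with an estimated correlation), which turned to 1 higher and 6 lower with library totals.

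A total of 6659 genes differed at the high dose, 3265 higher and 3394 lower, of which 443 and 1125 by at least 2-fold. With library totals 1267 were higher and 6134 lower, the median of all genes having moved to -0.30. The share of counts from mitochondrial genes was 11.3 ± 0.95% at the high dose and 9.11 ± 1.37% in AMLN vehicle. Within ranges A and B, 2595 and 3222 genes were called, and 98.1% and 98.0% of the genes called without the range had the same direction within it (82.7% and 82.4% over all). The medians there were -1.02 and -1.77 for matrix (pooled -1.70) and 0.89 and 0.86 for amino acid catabolism (pooled 0.95).

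The order of the doses was examined in the 6659 genes called at the high dose. Of these, 6062 (91.0%) had fitted changes ordered from low through medium to high in the direction of the high dose, and with means of log2 CPM 89.8% had. With the high dose kept and the low- and medium-dose libraries regrouped in all 12870 ways, a test added after the data had been seen, the mean was 48.5% (SD 22%), and 18 regroupings, the real one included, reached 89.8% (exact permutation p = 0.0014, one-sided). Rarres1 was at 71.5 ± 14.9 CPM in AMLN vehicle, 46.8 ± 8.27 CPM at the low dose, where it was not called, 5.63 ± 2.12 CPM at the medium dose and 0.925 ± 0.353 CPM at the high dose. The high dose differed from the low dose in 5963 genes, 2934 higher and 3029 lower, or 1222 higher and 5549 lower with library totals. Within ranges A and B that contrast gave 3251 and 2703 genes, and 96.7% and 98.0% of the genes called without the range had the same direction within it (79.0% and 80.8% over all).

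**Figure D3:**
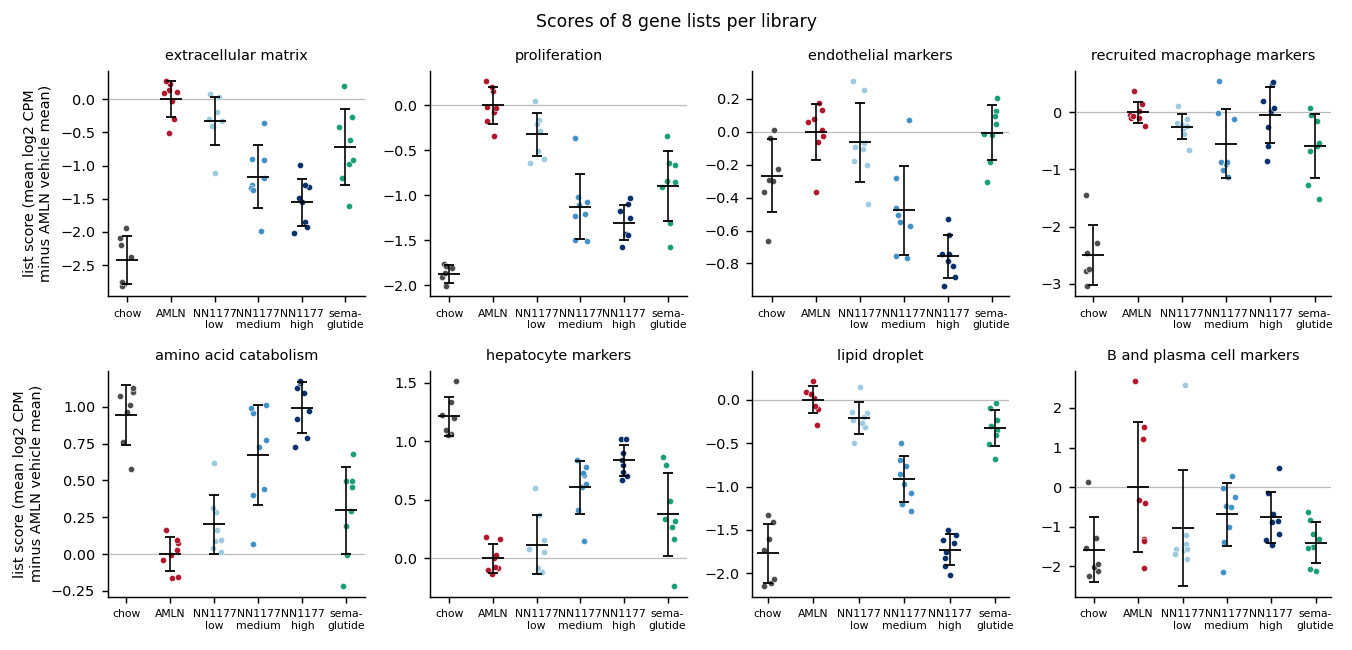
Scores of 8 gene lists, each the mean over list members of log2 CPM minus the AMLN vehicle mean, with 1 point per library and group mean ± SD. The extracellular matrix score averages -1.55 at the high dose, -0.72 on semaglutide and -2.42 on chow, and the endothelial score averages -0.76 at the high dose and -0.01 on semaglutide, where the sign of the endothelial median turns with the scaling.

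Semaglutide against AMLN vehicle asks what GLP-1 receptor agonism alone did. The proliferation gene Mki67 fell from 11.5 ± 3.78 to 4.49 ± 1.96 CPM (log2 -1.35 ± 0.27, adjusted p = 0.00316, n = 8 and 8) and Mcm6, a subunit of the replicative helicase, by -1.14 ± 0.21. Col3a1 fell from 304 ± 59.3 to 128 ± 82.0 CPM (log2 -1.25 ± 0.30, adjusted p = 0.0134) and Col1a1 from 204 ± 54.2 to 84.8 ± 50.8 CPM. Gsta1 (chromosome 9, 78230656 to 78242684), a glutathione transferase with close copies, fell from 25.7 ± 7.96 to 6.01 ± 3.52 CPM (log2 -2.08 ± 0.34, adjusted p = 0.00042). Upp2 (chromosome 2, 58567298 to 58792971), a uridine phosphorylase, rose from 181 ± 87.7 to 499 ± 213 CPM, and the leptin and prolactin receptor genes Lepr and Prlr rose 2.73-fold and 2.53-fold. Nnmt was at 51.9 ± 23.5 against 38.3 ± 16.3 CPM (adjusted p = 0.424).

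Proliferation genes fell in 21 of 32 cases on semaglutide (27 down and 1 up adjusted over the list alone; camera adjusted p = 2.09e-29), the 1 list called in any comparison with AMLN vehicle or between the high dose and semaglutide that kept its call with an estimated correlation (adjusted p = 0.00213). Extracellular matrix genes fell in 13 of 48 cases (25 down and 2 up adjusted over the list alone; camera adjusted p = 1.24e-20) and hepatocyte markers rose in 11 of 27 (20 adjusted over the list alone; camera adjusted p = 2.35e-13). Drug-metabolising P450 genes rose in 8 of 26 cases (13 adjusted over the list alone; camera adjusted p = 3.02e-08), with Cyp2c54, which has near-identical copies, up by log2 1.46 ± 0.36. The matrix, hepatocyte and P450 lists had adjusted p = 0.188 with an estimated correlation. With library totals 7 matrix genes were lower (9 with the number range as a covariate), and 7 hepatocyte markers, 5 P450 genes, 6 amino acid catabolism genes and 3 bile acid genes were higher. Amino acid catabolism genes rose in 9 of 42 cases (19 adjusted over the list alone; camera adjusted p = 1.33e-11, adjusted p = 0.275 with an estimated correlation), with Hpd, an enzyme of tyrosine breakdown, up by log2 0.82 ± 0.16. Bile acid genes rose in 6 of 27 cases (7 adjusted over the list alone; camera adjusted p = 2e-04, adjusted p = 0.207 with an estimated correlation), among them the bile acid importer Slc10a1 by log2 0.90 ± 0.17. B and plasma cell markers fell in 7 of 17 cases (16 adjusted over the list alone; camera adjusted p = 6.22e-08, adjusted p = 0.275 with an estimated correlation), from levels that varied widely in AMLN vehicle, such as 14.1 ± 23.8 CPM for Ighg1. Of 29 recruited macrophage markers 2 fell (5 down and 1 up adjusted over the list alone; camera adjusted p = 1.25e-08, adjusted p = 0.275 with an estimated correlation), and with library totals edgeR called 0 of them. Of 23 endothelial markers none passed the test with edgeR (camera adjusted p = 0.873, adjusted p = 0.955 with an estimated correlation; median 0.03, or -0.10 with library totals).

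In all, 479 genes differed on semaglutide, 256 higher and 223 lower, of which 20 and 105 by at least 2-fold. With library totals 93 were higher and 265 lower, the median of all genes having moved to -0.12. Within range A edgeR called 0 genes and within range B 1 gene. Without the libraries of range A edgeR called 0 genes (518 with an unadjusted p below 0.05) and without those of range B it called 48. Of these 48, 47 were tested within range B, and 43 (91.5%) had the same direction there (59.1% over all, and 62.1% in range A). The medians within ranges A and B were -1.57 and -0.85 for proliferation (pooled -1.10), -1 and -0.45 for matrix (pooled -0.61), 0.54 and 0.07 for amino acid catabolism (pooled 0.30) and -4.90 and -0.15 for B and plasma cell markers (pooled -2.51). The count ranged from 127 without replicate 3 to 877 without replicate 7 of the semaglutide group.

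The direct comparison of the high dose with semaglutide tests where the 2 treatments differ, at doses not known to match. Nnmt was 7.18-fold higher at the high dose (372 ± 90.3 against 51.9 ± 23.5 CPM; log2 2.84 ± 0.32, adjusted p = 1.63e-09, n = 8 and 8), Gls2 was higher by log2 2.40 ± 0.21 and Asns by 3.21 ± 0.46. Tuba8, an alpha-tubulin gene, was higher by log2 3.76 ± 0.27. Cidea was lower at 0.206 ± 0.229 against 16.1 ± 8.95 CPM, and Glul (chromosome 1, 153899944 to 153909723), the glutamine synthetase of hepatocytes around the central vein, was at 737 ± 117 against 1710 ± 215 CPM (log2 -1.22 ± 0.10). Col3a1 was lower by log2 -2.10 ± 0.31 and Scd1 by -1.41 ± 0.24.

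Amino acid catabolism genes were higher at the high dose in 30 of 42 cases and lower in 3 (30 and 4 adjusted over the list alone; camera adjusted p = 1.11e-12, adjusted p = 0.326 with an estimated correlation). Oxidative phosphorylation genes were higher in 30 of 42 (32 adjusted over the list alone; camera adjusted p = 2.96e-09) and ribosomal protein genes in 29 of 34 (30 adjusted over the list alone; camera adjusted p = 2.81e-11), both with adjusted p = 0.476 with an estimated correlation. With library totals 21 and 20 of these were higher, and 3 oxidative phosphorylation genes were lower. Endothelial markers were lower in 22 of 23 cases (22 adjusted over the list alone; camera adjusted p = 1.11e-12, adjusted p = 0.17 with an estimated correlation), with Stab2, a sinusoidal scavenger receptor, at 21 ± 3.71 against 47.7 ± 5.36 CPM. Lipid droplet genes were lower in 13 of 20 and higher in 3 (13 and 3 adjusted over the list alone; camera adjusted p = 4.73e-08, adjusted p = 0.0663 with an estimated correlation). P450 genes were lower in 13 of 26 and higher in 3 (15 and 3 adjusted over the list alone; camera adjusted p = 2.51e-05, adjusted p = 0.326 with an estimated correlation), with Cyp3a11 at 534 ± 230 against 3050 ± 450 CPM. Male-biased liver genes were lower in 15 of 30 and higher in 4 (16 and 4 adjusted over the list alone; camera adjusted p = 0.0539, adjusted p = 0.772 with an estimated correlation), including the organic anion transporter gene Slco1a1 by log2 -6.16 ± 0.88. Of 22 female-biased genes 6 were higher and 8 lower (6 and 8 adjusted over the list alone; camera adjusted p = 0.447, adjusted p = 0.843 with an estimated correlation), with a median of -0.14 where the test pointed up. Kupffer markers were lower in 7 of 12 cases (8 adjusted over the list alone; camera adjusted p = 0.00297, adjusted p = 0.476 with an estimated correlation), with Clec4f at 13.4 ± 13 against 53.0 ± 17.3 CPM. Recruited macrophage markers were higher in 12 of 29 and lower in 1 (13 and 1 adjusted over the list alone; camera adjusted p = 0.0024, adjusted p = 0.642 with an estimated correlation), with Gpnmb at 184 ± 80.1 against 34.1 ± 22.9 CPM and Trem2 at 17.3 ± 7.28 against 7.38 ± 4.48 CPM.

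A total of 4938 genes differed, 2305 higher and 2633 lower at the high dose, of which 313 and 641 by at least 2-fold. With library totals 1232 were higher and 3869 lower, the median of all genes having moved to -0.17. The share of counts from mitochondrial genes was 11.3 ± 0.95% at the high dose and 8.70 ± 0.60% on semaglutide. Within ranges A and B, 2825 and 1390 genes were called, and 83.6% and 97.6% of the genes called without the range had the same direction within it (66.1% and 79.0% over all). The medians there were -0.67 and -0.78 for endothelial markers (pooled -0.74), 1.09 and 0.30 for recruited macrophage markers (pooled 0.45) and -0.18 and -1.25 for matrix (pooled -0.98). The medium dose differed from semaglutide in 642 genes, 258 higher and 384 lower (377 to 956 when 1 library is left out), with 82 called within range A and 46 within range B. The low dose differed in 16 by edgeR, 12 higher and 4 lower, with 0 called in either range. That count was 4 to 69 when 1 library is left out and 322 with limma-voom.

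Chow shows how far each treatment moved the livers of AMLN-fed mice towards those of chow-fed mice. Of the 8110 genes called for the diet, 3078 (38%) were called in the opposite direction and 40 in the same direction at the medium dose. At the high dose 4415 (54.4%) were opposite and 256 the same, on semaglutide 464 (5.7%) were opposite and 2 the same, and at the low dose Cfd alone was opposite. Independent lists of these sizes would give 1079, 1906 and 138 opposite genes for medium, high and semaglutide. Simulations with no drug effect gave at most 1, but at most 1 gene was called for a drug in any of them. They therefore could not show whether shared libraries push called drug genes into the opposite direction. The slope of the drug effect on the diet effect was -0.11 at the low dose and -0.33 at the medium dose. It was -0.41 at the high dose and -0.27 on semaglutide. Sharing AMLN vehicle libraries alone gave -0.03 in simulations, whose genes varied independently, without shifts that many genes of a library share. Slopes of single libraries (log2 CPM minus the AMLN vehicle mean) averaged 0 ± 0.08 in AMLN vehicle and -0.10 ± 0.13 at the low dose. They averaged -0.32 ± 0.16 at the medium dose, -0.37 ± 0.11 at the high dose and -0.25 ± 0.20 on semaglutide. Low-dose replicate 3 was at -0.40 and the other low-dose libraries at -0.137 to 0.009. With separate AMLN vehicle libraries for each comparison the slopes were -0.08, -0.29, -0.36 and -0.22. The covariance of the 2 effects was -0.12, -0.36, -0.44 and -0.29, against a simulated -0.04. Lacking shifts shared by many genes of a library, the simulations cannot set the low-dose values apart from such shifts. With drug and diet effects both taken within range A or B, the slopes were -0.17 and 0.02 at the low dose, -0.35 and -0.24 at the medium dose, -0.39 and -0.26 at the high dose and -0.44 and -0.09 on semaglutide. With the diet effect of all libraries in place of the range's own, they were -0.16 and 0.05, -0.33 and -0.36, -0.36 and -0.40, and -0.46 and -0.12.

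**Figure D4:**
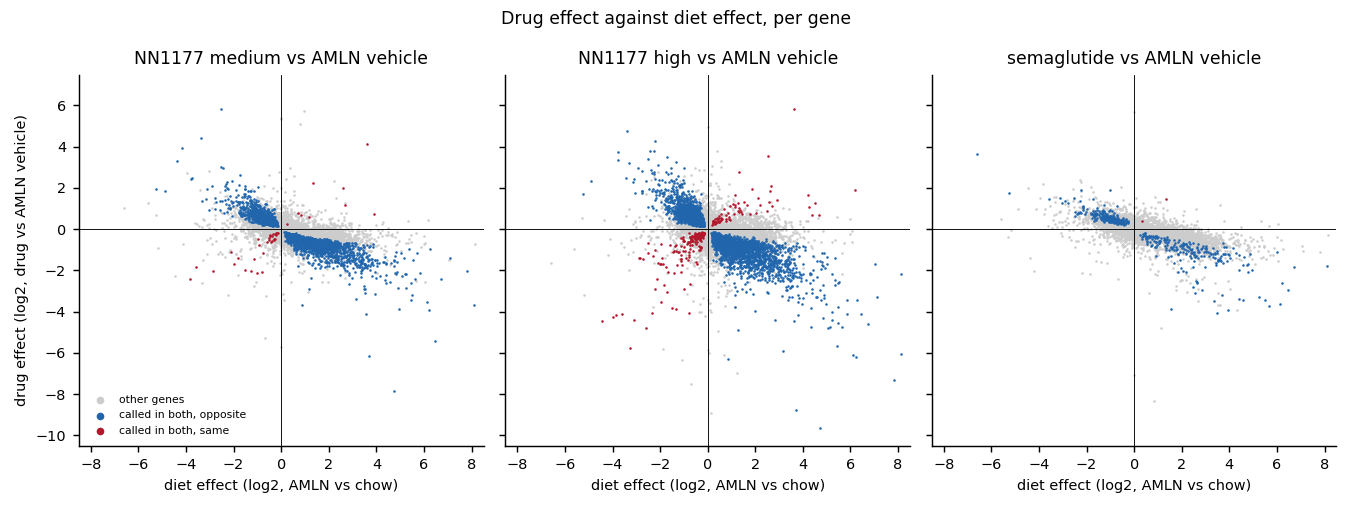
Log2 fold change of each tested gene under drug (vertical axis, against AMLN vehicle) and under diet (horizontal axis, AMLN vehicle against chow), with genes called in both comparisons in blue where the directions are opposite and in red where they are the same, and 4 genes lying outside the axes. The high dose has 4415 opposite and 256 same-direction genes, and semaglutide 464 and 2.

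Against chow itself, the high dose differed in 5542 genes, 2758 higher and 2784 lower, and semaglutide in 5756, 3033 higher and 2723 lower. With library totals these were 4953 higher and 1110 lower for the high dose and 7174 higher and 456 lower for semaglutide. Of the 8110 diet genes, 3498 were still called in the diet's direction at the high dose and 394 in the other direction, with a further 1650 genes called that the diet had not changed by the test. For semaglutide these counts were 5467, 2 and 287. Within ranges A and B the high dose gave 1904 and 263 genes, and semaglutide 555 and 554. Of the genes called without the range, 95.9% and 91.4% had the same direction within it for the high dose (77.2% and 73.7% over all) and 82.8% and 94.3% for semaglutide (69.3% and 76.5%).

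Between the high dose and semaglutide, 216 genes were higher and 194 lower under both against AMLN vehicle, 9 were lower at the high dose and higher on semaglutide, and none went the other way by edgeR. Independent lists would share 59 and 53 genes. Simulations with no effect gave 0. At most 1 gene was called per treatment in them, so they could not show an overlap from shared libraries. Separate AMLN vehicle libraries for each treatment gave means of 22.7 and 30.9, where independent lists of those smaller sizes would share 5.55 and 9.54. The fold changes correlated across genes, which are not independent replicates, at r = 0.50, where shared controls alone gave 0.49 in simulations. With separate AMLN vehicle libraries r averaged 0.32 (0.23 to 0.37). The covariance was 0.16, or 0.13 with separate libraries, against a simulated 0.04. The simulated genes varied independently here too.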

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

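The tests of hepatocyte share, of Cyp3a copies, of immune cells of every kind and of chance order were chosen after the results were seen. The rules that singled out the values here were written before the values were seen. In 204 groups of values (panel genes and list scores within a group), 1 library stood apart from the others in 25. The gap test flags about 1 group in 20 by chance, or 10 here, if values are normally distributed. CPM values entered without logs, so more than 10 flags may arise by chance. A further 9 genes were called in opposite directions by the high dose and semaglutide. None of these libraries was left out, and the cause was not tested.

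Chow replicate 2 stood above the other chow libraries in 4 genes: Saa1 at 3980 CPM (others 12.1 to 1220), Nnmt at 221 CPM (51.1 to 114), Igfbp1 at 58.4 CPM (4.04 to 14) and Ccl2 at 0.938 CPM (0 to 0.32). Chow replicate 1 had Fgf21 at 2.40 CPM (0.176 to 1.02) and chow replicate 7 had Acta2 at 14.2 CPM (1.57 to 4.92). The Acta2 value widens the chow SD, so the test of Acta2 between the diets rests on a spread set largely by 1 library.

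In AMLN vehicle, replicate 7 had Pck1 at 304 CPM, below the other libraries (800 to 1140), and Trem2 at 18.7 CPM, above them (7.68 to 12.3). Igfbp1 was at 82.3 CPM in replicate 3 (21.9 to 50.3), and replicate 1 had an endothelial score of -0.368 (others -0.062 to 0.174). At the low dose, replicate 3 had the lowest extracellular matrix score, -1.10 (others -0.402 to 0.083), and the highest Cps1, 2630 CPM (1430 to 1940). Replicate 6 had Igfbp1 at 118 CPM (9.43 to 58.9) and replicate 7 a cholesterol synthesis score of -0.463 (0.124 to 0.57).

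At the medium dose, replicate 3 stood apart in 2 values, with a proliferation score of -0.362 (others -1.51 to -1.01) and Trem2 at 21.1 CPM (4.51 to 10.6). Replicate 8 had Clec4f at 110 CPM (13.7 to 37.4), Igfbp1 at 97.8 CPM (21.4 to 45.2) and a cholesterol synthesis score of 1.16 (-0.029 to 0.525). At the high dose Nnmt was at 565 CPM in replicate 2 (252 to 400) and Ccl2 at 3.49 CPM in replicate 5 (0.323 to 1.26). On semaglutide the values apart were Fgf21 at 6.34 CPM in replicate 2 (0.921 to 3.01), Pck1 at 2330 CPM in replicate 3 (795 to 1300), Hmgcr at 112 CPM in replicate 5 (42 to 73.6) and Clec4f at 89.4 CPM in replicate 1 (35.3 to 58.8).

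The 9 genes that fell at the high dose and rose on semaglutide, by edgeR against the same AMLN vehicle libraries, were tested directly between the treatments. The difference, high dose minus semaglutide, was log2 -5.60 for Cyp2c54, -2.90 for Cnmd, -2.75 for Cyp2c37, -2.66 for Sult2a8 and -1.68 for Smad9. It was -1.22 for Glul, -0.91 for Cyp27a1, -0.77 for Hpgd and -0.50 for C1ra. Cyp2c54 and Cyp2c37 have near-identical copies, so reads may be divided unevenly between them: the summed Cyp2c counts differed by log2 -0.83 between the treatments. Against AMLN vehicle the sum rose on semaglutide (log2 0.80, exact permutation p = 0.00404) and did not fall at the high dose (log2 -0.04, exact permutation p = 0.819). The rise of Cyp2c54 on semaglutide lost its call with the 2 groups alone (adjusted p = 0.0611).

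The first pattern weighed is the lower P450 and Mup expression at the high dose than on semaglutide. A smaller share of hepatocytes would lower their markers too, yet the median hepatocyte marker was higher by log2 0.38 (0.24 with library totals). Marker RNA in bulk liver cannot separate cell share from expression per cell, so a smaller share is not excluded. The weaker of the medians within ranges A and B of the 28 genes called lower was -2.76. Those genes were chosen with the same libraries, so this cannot exclude the number range. With the range as a covariate, the list medians were -0.63 for P450 and -0.94 for male-biased genes (pooled -0.58 and -0.95). Reads moving between copies could account for part of the drop in single Mup and Cyp2c genes, as the smaller drop of the 2 family sums was -0.83. For Cyp3a it cannot account for the whole drop, as the family sum was 919 ± 232 against 3480 ± 444 CPM, a difference of -1.95. Part of the drop of single Cyp3a genes could still come from it.

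The second pattern is the higher recruited macrophage score at the high dose (-0.05 ± 0.49) than on semaglutide (-0.59 ± 0.57). AMLN vehicle was at 0 ± 0.19, so for the mean score the gap lies in the lower semaglutide value. Single members can differ: against AMLN vehicle, 6 of 29 were called higher and 3 lower at the high dose (1 and 6 with library totals), and 0 and 2 on semaglutide. Scaling is an unlikely source, as the lower of the list medians with DESeq2 size factors and with library totals was 0.25. The lower of the medians within ranges A and B was 0.30, but the number range stays open. In range A the scores were -0.257 to 0.502 at the high dose and -1.512 to -0.582 on semaglutide. In the other ranges they overlapped, at -0.854 to 0.538 and -0.53 to 0.067. More immune cells of every kind would likely raise the T and NK, B and plasma, and dendritic lists together, and the lowest of their differences was -0.42 (the dendritic list). The differences in score were 0.54 for recruited macrophages (exact permutation p = 0.064, 0.0896 after adjustment), 0.64 for B and plasma cells (0.0859 after adjustment), -0.42 for dendritic cells (0.0859) and -0.36 for T and NK cells (0.134), so none of the 4 passed and the explanation stays open. Kupffer scores differed by -1.08 (exact permutation p = 0.000622, 0.00218 after adjustment).

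The third pattern is that semaglutide libraries of range A lay further towards chow than those of the other ranges, at -0.41 against -0.09 on the diet axis. Depth is an unlikely source, since thinning range A changed the difference by 0.5%. Chance stays open: the exact permutation p was 0.0286, the smallest that 35 splits of 8 libraries allow. After adjustment over 6 groups it was 0.171. The smallest p of 1 group alone cannot pass that adjustment, so the adjusted value does not decide the question. Judged from the low dose (-0.12, exact permutation p = 0.257), a shift of range A in every group would come to 37.4% of it. No interval was computed for this share, so it is not an upper limit. The other groups did not show such a shift (medium 0, AMLN vehicle 0.01, chow 0.07, high 0.11). EdgeR called 0 genes for a different semaglutide effect between ranges A and B. An unadjusted p below 0.05 was found for 719 genes (5.1%), near the nominal share for this threshold. For the low, medium and high doses the same test gave 2.2%, 2.8% and 2.2%, so semaglutide had the largest share. The lack of called genes therefore does not exclude a different effect.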

How the results depend on the processing

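Most alternatives here were planned; library totals, leaving out the 2 shallowest libraries, leaving out a number range and the number series were chosen after the data had been seen. The cause was not tested for any of these changes. The counts for the diet, the high dose against AMLN vehicle, semaglutide and the low dose, and semaglutide against chow stayed within 1.5-fold under every alternative.

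Leaving out ranges A and B, which removes 20 and 12 of the libraries, gave 0 and 0 genes for the low dose, 1830 and 1682 for the medium dose (3760 with all), 0 and 48 for semaglutide (479 with all) and 1 and 0 for the low dose against semaglutide. The medium dose against semaglutide gave 236 without range B, and the high dose against chow 3530 without range A. Title numbers place 41 libraries in 9 series that step through the groups. Same-series libraries of different groups deviated from their group means with a mean correlation of 0.047 (-0.415 to 0.511 over 79 pairs). It was 0.027 for other pairs within a range and -0.013 for pairs from different ranges. Of 41 libraries, 14 correlated best with a library of their own series. The number expected with no pairing was not computed, so these values do not settle whether the numbers pair the samples. With the series as a replicate block edgeR called 0 genes for the low dose, 2357 for the medium dose and 24 for semaglutide, and the same libraries without the block gave 0, 3026 and 174. The block moved no other count over 1.5-fold.

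For the low dose (1 gene by edgeR, 556 unadjusted), the range covariate, leaving out shallow libraries and leaving out range D each gave 0, limma-voom gave 2, and library totals and the 2 groups alone each gave 3. Omitting 1 library gave 0 to 13: among NN1177 low libraries 2 without replicate 1, 13 without 2, 3 without 4, 5, 6 or 7, and 0 without 3 or 8; and 0 without AMLN vehicle replicates 5, 7 or 8. For semaglutide (479), leaving out range D gave 207, the 2 groups alone 319 and limma-voom 1091. Omitting 1 library gave 127 to 877: without semaglutide replicates 1, 2, 3, 4 and 7 the counts were 304, 204, 127, 161 and 877, and without AMLN vehicle replicates 2 and 8 they were 240 and 298.

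For the medium dose against semaglutide (642), the 2 groups alone gave 361 and limma-voom 1138, and omitting 1 library gave 377 (without NN1177 medium replicate 6) to 956. For the low dose against semaglutide (16), DESeq2 size factors gave 27, a mean of at least 1 CPM 26, the range covariate 30, leaving out range D 35, the DESeq2 test 59, limma-voom 322 and the 2 groups alone 4. Omitting 1 library gave 4 to 69: without NN1177 low replicates 1, 3, 4, 5 and 8 the counts were 8, 48, 9, 6 and 25, and without semaglutide replicates 2, 3, 4, 5, 7 and 8 they were 6, 7, 4, 6, 69 and 29. Omission ranges elsewhere were 7736 to 8093 (diet), 2944 to 4402 (medium), 6246 to 6710 (high), 4488 to 4959 (high against semaglutide), 5566 to 6079 (high against low), 5089 to 5661 (high against chow) and 4651 to 6175 (semaglutide against chow).

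With an estimated correlation camera called 0 lists for the diet, the low, medium and high doses and the high dose against semaglutide, and 1 for semaglutide, where the preset called 26, 23, 23, 17, 20 and 25. Fry called 32 for the diet, 0 for the low dose, 21 for the medium dose and 26 for the high dose. It called 14 for semaglutide and 26 for the high dose against semaglutide. With separate AMLN vehicle libraries for each comparison (means of 20 random divisions), diet genes called the opposite way fell to means of 0.1 (low), 1668.7 (medium) and 64 (semaglutide), and to 0 for the low dose with the range covariate. Fewer genes were called for the drugs then too, at means of 2202 (medium) and 83 (semaglutide), and of the genes called for diet and drug, 1669 of 1698 and 64 of 65 were still opposite. The slopes with separate libraries were -0.075 (low), -0.287 (medium) and -0.223 (semaglutide), and the overlap of the high dose and semaglutide fell to 22.7 genes up and 30.9 down.

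Of the 86 gene results named in the report, 85 kept their direction and side of the threshold with DESeq2 size factors, 84 with the DESeq2 test, 84 with the range covariate and 81 with library totals. With the 2 groups alone 82 of the 85 that could be tested did. The 1 reversal was Gcgr between the diets, at log2 0.06 (adjusted p = 0.351) with library totals. Cfd at the low dose lost its call with the DESeq2 test (adjusted p = 0.29) and the range covariate (adjusted p = 0.114). Trem2 at the high dose lost its call with DESeq2 size factors (adjusted p = 0.0558), the DESeq2 test (adjusted p = 0.0676) and library totals (adjusted p = 0.302). On semaglutide, Cyp2c54 lost its call with the 2 groups alone (adjusted p = 0.0611) and Ighg1 with the range covariate (adjusted p = 0.104). The other gene results that differed gained a call: Acta2 between the diets with library totals (adjusted p = 0.0181), and at the high dose G6pc and Hmgcr with the 2 groups alone (adjusted p = 0.0272 and 0.0353) and with library totals (adjusted p = 0.039 and 0.0273). Of the 52 list results, 45 lost their call with an estimated correlation and 3 with fry, and none reversed in camera's direction. Calls were gained by the stress-response list at the high dose with fry (adjusted p = 0.00684) and Kupffer markers between the diets with library totals (adjusted p = 0.00747). Male-biased genes between the high dose and semaglutide gained theirs with DESeq2 size factors (adjusted p = 0.0488) and with no low-count filter (adjusted p = 0.0179). Sequencing depth limits what can be said of Glp1r, with no more than 8 counts in any library.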

Other observations

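The family sums given in this section were chosen after the results were seen, and the random regroupings before. Alpha-1-antitrypsin counts, not described so far, were summed over the 5 Serpina1 copies because Salmon divides reads among them. The sum was 30300 ± 3490 CPM at the high dose, 10700 ± 1710 CPM in AMLN vehicle, 15100 ± 5100 CPM on semaglutide and 38800 ± 7510 CPM on chow. The high-dose libraries did not overlap with AMLN vehicle (log2 1.51, exact permutation p = 0.000155) or semaglutide (log2 1.07, exact permutation p = 0.000155). The 21 Mup genes, major urinary proteins whose expression is higher in males, summed to 14400 ± 4810 CPM at the high dose and 22900 ± 6670 CPM in AMLN vehicle (log2 -0.68, exact permutation p = 0.0159). The 6 Cyp4a genes, fatty acid hydroxylases, summed to 925 ± 288 CPM at the high dose and 845 ± 334 CPM in AMLN vehicle (exact permutation p = 0.553).

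Regrouping the libraries of a comparison at random asks how many calls other groupings of them give. Of 25 groupings including the real one, only the real one (1) reached its number of genes in every comparison but the low dose with AMLN vehicle, where 5 did. The highest count of another grouping against the real one was 862 against 8110 for the diet, 2 against 1 for the low dose, 695 against 3760 for the medium dose, 1276 against 6659 for the high dose and 1 against 479 for semaglutide. It was 564 against 4938 for the high dose and semaglutide, 2 against 642 for the medium dose and semaglutide, 3 against 16 for the low dose and semaglutide, and 2943 against 5963 for the high and low doses. Against chow it was 245 of 5542 for the high dose and 1433 of 5756 for semaglutide. Random groupings can keep most of the real one or of its mirror image, so these highest counts are not levels of chance alone. The grouping with 2943 had 1 high-dose library in the place of the high dose. The grouping with 695 kept 7 medium-dose libraries in place. The median of the other groupings was 2 genes for the diet and 0 in every other comparison. The single low-dose gene may be a chance call, as 5 of 25 groupings reached its count.

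For lists called by camera with the preset correlation, chance groupings often did as well, so the preset likely overstates list calls. As many lists came up in 3 of 25 groupings for the diet (real 26, highest other 28), 4 for the medium dose (23 and 25), 11 for the high dose (17 and 29) and 6 for the high dose and semaglutide (20 and 22). Only the real grouping (1 of 25) reached the count for the low dose (23 and 20) and for semaglutide (25 and 24).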
